A study of Homo sapiens with 7 samples.

How the data were processed

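Gene expression was measured in HT1080 cells, an established human fibrosarcoma line, on 7 Affymetrix arrays of the U133 Plus 2.0 design with 54675 probe sets each. Per the labels, the cells were plated a day ahead, the medium was replaced, and a single compound or serum was present for 2 h. The labels give no time, medium change or solvent for the untreated culture, and they do not say whether the replaced medium held fetal bovine serum or where the control serum came from. A difference from the untreated array can therefore include those steps besides the compound or serum. The values were the deposited signal intensity of each probe set, which the authors computed with MAS5 according to the submitters' processing notes. Neither the MAS5 version nor detection calls were given in the sources used here. The values lay on a linear scale, and the mean of each array after trimming 2% at both ends was checked and lay at 1000. No count of molecules underlies an array signal, so the number of arrays limits the precision.

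Probe sets were assigned to genes with the platform's annotation table, and gene symbols were brought up to date with a RefSeq table for the human assembly GRCh38. Of the probe sets, 41097 were assigned to 1 gene, 1801 named several genes and were left out, and 11777 had no entry and were left out. The 62 control probe sets were used for quality values alone. Signals under the 25th percentile of all values, 34.9, were raised to it, and the signals were put on the log2 scale. Each gene was read from the probe set with the highest mean log2 signal over the 7 arrays, which gave 19775 genes. The 9888 genes with a mean log2 signal at or above the median of all genes, 8.07, were compared. Genes missing from the annotation used here were not analysed here.

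Each group held 1 array, so the groups could not be compared with a replicate error or a p-value, and the arrays gave no pairs. Differences are log2 signal of the first array minus log2 signal of the second, and a gene was counted as higher or lower when it differed by at least 2-fold. The 4 compounds and the control serum were compared with the untreated array, and the serum taken after pycnogenol with the control serum. The 4 compounds were also compared with one another in 6 pairs. The standard deviation (SD) of the log2 differences over genes was computed for all 21 pairs of arrays.

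The 26 gene lists were fixed by name. They covered the immediate early and serum response, NF-kB and inflammatory cytokines, the NRF2 antioxidant response, AhR and xenobiotic metabolism, p53 targets, apoptosis regulators, G1/S and DNA replication, G2/M and mitosis, and matrix, proteolysis and invasion. Further lists held heat shock genes, the unfolded protein and ATF4 response, sterol biosynthesis, hypoxia and glycolysis, the interferon response, TGF-beta and BMP targets, glucocorticoid targets, the circadian clock, and PPAR and lipid handling. The others held sirtuins, AMPK and mitochondrial biogenesis, metallothioneins and the zinc response, angiogenesis factors, replication-dependent histones, cytosolic ribosomal proteins, oxidative phosphorylation, blood cell markers, and epithelial and endothelial markers. For each list the median log2 difference of its members above the signal filter was set against 10000 random lists of the same size, drawn from the same 20 expression bins. A median outside the central 95% of the random medians is called outside its random range. That position describes these arrays, since genes are not independent replicates. The 2 marker lists of other cell types had too few members above the filter for a median.

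The rule for named genes took, in each comparison with a control, the 10 largest differences in each direction among genes at or past 2-fold. Their brighter signal had to exceed the 75th percentile of its array, and their direction had to hold under quantile normalization and pairwise loess. From each list the 3 members with the largest absolute difference were named, and so were genes past 2-fold in the same direction under all 4 compounds. The comparisons, lists, rule and most alternative settings were chosen before the data were examined. Genes from the pairs of compounds, and the comparison of both serum arrays with the other 5, were chosen later.

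The alternative settings were quantile normalization, pairwise loess with a span of 0.3, centring on the median, no signal filter, a filter at the 75th percentile, no floor, and a floor at the 40th percentile. Further settings took the mean of all probe sets of a gene, left out probe sets with the suffix _x_at or _s_at, used thresholds of 1.5-fold and 3-fold, and used other reference arrays. Where a gene had a second probe set whose mean passed the signal filter, its direction was compared with that of the first, with exact Clopper-Pearson 95% intervals for the share. It was the brightest of the other probe sets, and dimmer ones were left out of the share. These intervals treat genes as independent.

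The procedure was tested on simulated data with normal noise, whose SD in each expression bin was that seen between the 4 compound arrays. Genes were simulated as independent. Probe sets noisier than others of like signal were not covered, so counts for unchanged genes can be too low. The SD can also include real differences between the compounds, which would make those counts too high. At the 2-fold threshold it recovered 4.6% of genes simulated with a 1.5-fold change, 48.9% with a 2-fold change and 98.9% with a 3-fold change, and it called 20.7 unchanged genes per comparison. Of simulated lists, 4.0% without a shift and 94.5% with a log2 shift of 0.20 fell outside the random range. The software was python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.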

Results

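HT1080 fibrosarcoma cells were profiled in 7 cultures, each on 1 array. In 4 of them a single plant polyphenol was present for 2 h, namely catechin at 11.25 ng/ml, epicatechin at 6.25 ng/ml, taxifolin at 6.25 ng/ml or resveratrol at 2195 ng/ml. Another 2 held serum at 5% for 2 h, either control serum or serum from patients given pycnogenol, an extract of pine bark that contains catechin, epicatechin and taxifolin. The last culture was untreated, and the labels do not say whether it had the medium change or a solvent. There were no replicates, so no difference could be set against a replicate error, and all values describe single arrays. The median signal per array ran from 114 to 136 on the deposited scale. Signals under the filter's 269 were not shown to be above background, as no detection calls were at hand, so differences that rest on such a signal are given with it and their size is uncertain.

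The comparisons asked how gene expression in these cells differed with each compound and with serum taken after pycnogenol. The 2 serum arrays stood apart from the 5 arrays without test serum. Among the 5, the SD of log2 differences over genes ran from 0.235 to 0.282 in the 10 pairs, and 30 to 72 genes differed by at least 2-fold. In the 10 pairs of a serum array with one of the 5, the SD ran from 0.323 to 0.387, and 99 to 228 genes differed by at least 2-fold. The 2 serum arrays differed from each other with an SD of 0.277 and 53 genes.

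**Figure D1:**
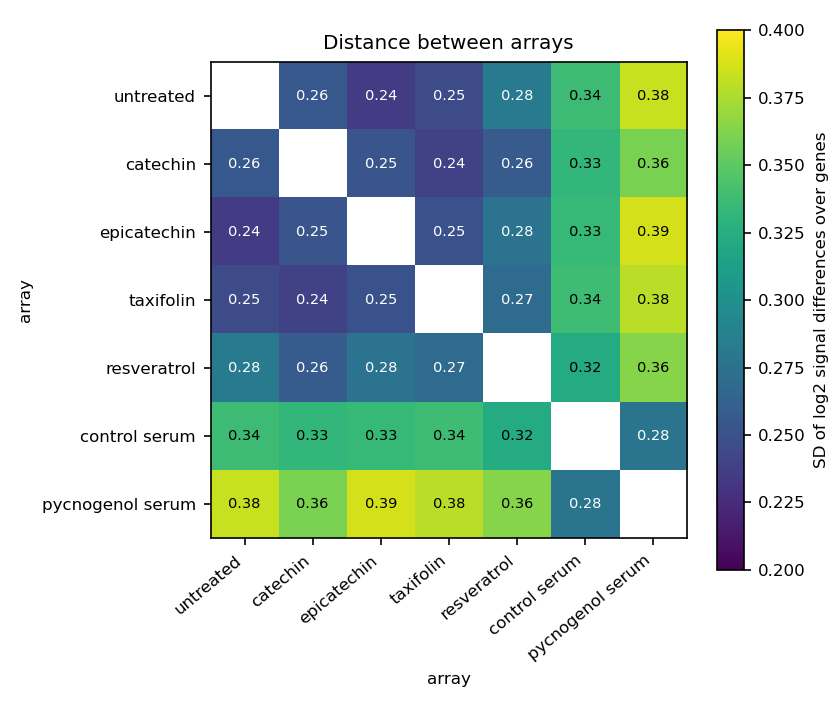
SD over 9888 genes of the log2 signal difference for each of the 21 pairs of the 7 arrays, as a heatmap with both axes listing the arrays. Pairs of a serum array with an array without test serum hold the values from 0.323 to 0.387, and pairs without test serum those from 0.235 to 0.282.

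With control serum against the untreated culture, genes of TGF-beta and BMP signalling were higher and genes of sterol synthesis were lower. Of 17 TGF-beta and BMP targets, 15 lay above 0 and 5 were higher by at least 2-fold, with a list median of 0.80 (log2) against a random range of -0.14 to 0.16. That median was 0.44 with the filter at the 75th percentile and 0.53 with the mean of all probe sets. ID2 and ID3, inhibitors of DNA-binding helix-loop-helix factors, differed by 1.78 and 1.53, PMEPA1, a membrane protein that restrains TGF-beta signalling, by 1.61, and the SMAD corepressor SKIL by 1.36. TGFBI differed by 1.09 and the inhibitory SMAD7 by 0.94. All 18 sterol genes lay below 0, with a list median of -0.58 and a random range of -0.13 to 0.16. In that list 4 genes were lower by at least 2-fold: MSMO1, a sterol demethylating oxidase, at -1.80, HMGCS1, an early enzyme of the mevalonate pathway, at -1.74, INSIG1, which holds back SREBP processing, at -1.73, and the sterol carrier STARD4 at -1.15.

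Heat shock genes lay above 0 in 15 of 15 cases with a median of 0.28 and none at 2-fold, led by HSPH1 at 0.75 and DNAJB1 at 0.65. Of 28 G1/S and replication genes, 24 lay above 0 with a median of 0.21, with E2F1 at 0.76 and CCND3 at 0.75. The unfolded protein and ATF4 list had a median of -0.24, with 27 of 30 members below 0 and 2 lower by at least 2-fold, the pseudokinase TRIB3 at -1.31 and CTH, a cysteine-forming enzyme, at -1.06. The PPAR and lipid list had a median of -0.23 over 13 members, with LPIN1 at -0.81 and PPARA, which read 222 with control serum, at -0.88, none at 2-fold. Outside these lists' main themes, EDN1, which encodes the vasoconstrictor endothelin-1, differed by 1.85 and heme oxygenase HMOX1 by 1.71. Among cytokine genes, IL1B was lower at -1.66 and IL24 at -1.62, while the chemokine gene CCL20 was higher at 1.21. The NF-kB and cytokine list median of -0.017 lay inside its random range, with 9 members above and 9 below 0. The interferon-induced IFIT2 was at -1.70, with a signal of 176 with control serum, and PLAT, tissue plasminogen activator, at -1.17. Other named genes were FAXDC2 at 1.81, RARS1, an arginyl-tRNA synthetase, at 1.501, NREP and VAV2 both at 1.23, RAB39B at -2.11 with a signal of 232, PNRC1 at -1.83, SLFN5 at -1.56 and AGO4 at -1.43. TRMT10A, a tRNA methyltransferase, was at -1.89, but at 0.16 when read without _x_at and _s_at probe sets.

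Over all genes, 44 were higher and 75 lower by at least 2-fold with control serum, and the split was 62 and 59 under quantile normalization, while the filter at the 75th percentile left 26 genes. The mean of the untreated and 4 compound arrays as reference gave 64 genes, 20 higher and 44 lower, but a mean of arrays holds less noise than 1 array. Where such a gene had a second probe set above the filter, it moved in the same direction for 33 of 38 genes, 86.8% with an interval of 71.9% to 95.6%. The share does not cover the rest of the 119 genes. Second probe sets gave 2.90 for PMEPA1, -2.11 for INSIG1, -1.50 for IL1B, 0.75 for EDN1 and -0.057 for VAV2. With the mean of all probe sets, the G1/S and PPAR medians came to lie inside their random ranges, at 0.11 and -0.00041, while the G1/S median was 0.34 without _x_at and _s_at probe sets.

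**Figure D2:**
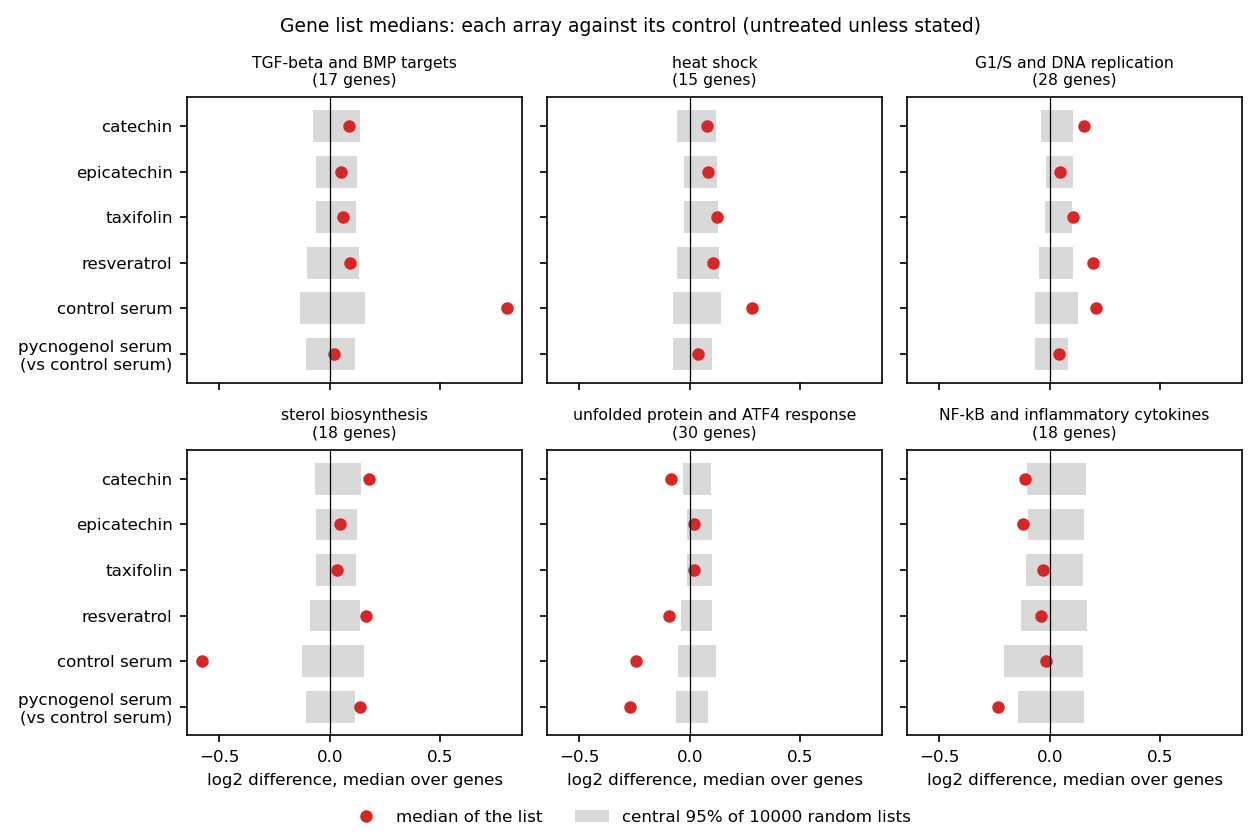
Median log2 difference of 6 gene lists (points, x axis) in each comparison (y axis), with the central 95% of 10000 random lists as grey bars. In the control serum comparison TGF-beta and BMP targets lie at 0.80 and sterol biosynthesis at -0.58, both outside the grey bar.

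With serum taken after pycnogenol, set against control serum, genes of the unfolded protein and ATF4 response and immediate early genes were lower, while heat shock and NRF2 genes stayed inside their random ranges. The unfolded protein and ATF4 list had a median of -0.27 against a random range of -0.061 to 0.080, with 23 of 30 members below 0, and a median of -0.54 without _x_at and _s_at probe sets. Lower by at least 2-fold in it were DDIT4, an inhibitor of mTORC1, at -2.71, the transcription factor ATF3 at -1.0005, and CHAC1, a glutathione-degrading enzyme, which read 1077 with control serum and 143 with pycnogenol serum, a difference of -2.91. ATF3 lay at 0.15 with the mean of all its probe sets. HERPUD1, a factor in clearing misfolded proteins, was at -0.96 and XBP1 at -0.81. Of the chaperone genes in the list, HSP90B1 at 0.19, DNAJC3 at 0.18 and CALR at 0.035 lay above 0, and HSPA5 was at -0.19. The immediate early list had a median of -0.14 with 24 of 32 members below 0, including the transcription factors KLF4 at -1.33 and EGR1 at -1.44, the latter with a signal of 175. The NF-kB and cytokine list had a median of -0.24 with 11 of 18 members below 0, with IL1A, a proinflammatory cytokine gene, at -2.20 with a signal of 193, IL1B at -0.70 and NFKBIA, an NF-kB inhibitor, at 0.59. The NF-kB median lay inside its random range at -0.019 without the signal filter and also with the filter at the 75th percentile, and the immediate early median did so without _x_at and _s_at probe sets.

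Among glucocorticoid targets KLF9 at -1.52 and TSC22D3 at -1.50 were lower by at least 2-fold, and DUSP1 at -0.91 fell short of that. The list median of -0.10 lay inside its random range. Sterol genes had a median of 0.14 and ribosomal protein genes one of 0.089, both outside their ranges and with no member at 2-fold. With the untreated array as reference the sterol median was -0.43, the opposite direction. That reference adds the difference of control serum from the untreated array, where the sterol median was -0.58. The sterol median came inside its range without _x_at and _s_at probe sets, and the ribosomal median under 5 settings, at 0.0038 with quantile normalization. The other named genes were RARS1 at -1.80, FAXDC2 at -2.70 with a signal of 150, KDM7A, a histone demethylase, at -1.51 and TUBE1 at -1.31. Higher were LINGO3 at 2.01 from a signal of 223, TRMT10A at 1.83, PLEC, the cytoskeletal linker plectin, at 1.69, SPEN at 1.32, HLA-F-AS1 at 1.24, BTF3P12 at 1.14, KCNAB1 at 1.09 and ATXN2 at 1.03. TRMT10A lay at -0.14 without _x_at and _s_at probe sets, and the Mediator subunit MED26 at 1.195 but at -0.11 with the mean of all its probe sets.

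In total 22 genes were higher and 31 lower by at least 2-fold, and 6 genes were counted with the filter at the 75th percentile. Of 14 genes past 2-fold in both serum comparisons, which share the control serum array, 13 had opposite directions, among them FAXDC2, RARS1, TRMT10A, LINGO3 and KCNAB1. The correlation of both comparisons across genes was -0.232, where unchanged arrays sharing a control gave -0.500 in simulation. Those 5 lay at -0.90, -0.30, -0.058, 0.85 and 0.030 with pycnogenol serum against the untreated array. On that same reference DDIT4 lay at -3.25 and KLF9 at -2.04, CHAC1 at -3.16 and IL1A at -2.99 with the low signals already given, and the count rose to 221 genes. These values and the count include the difference of control serum from the untreated array. Second probe sets had the called direction for 8 of 11 genes, 72.7% with an interval of 39.0% to 94.0%, with KLF9 at -0.30, KDM7A at -0.85, SPEN at 0.25 and KCNAB1 at 0.59.

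**Figure D3:**
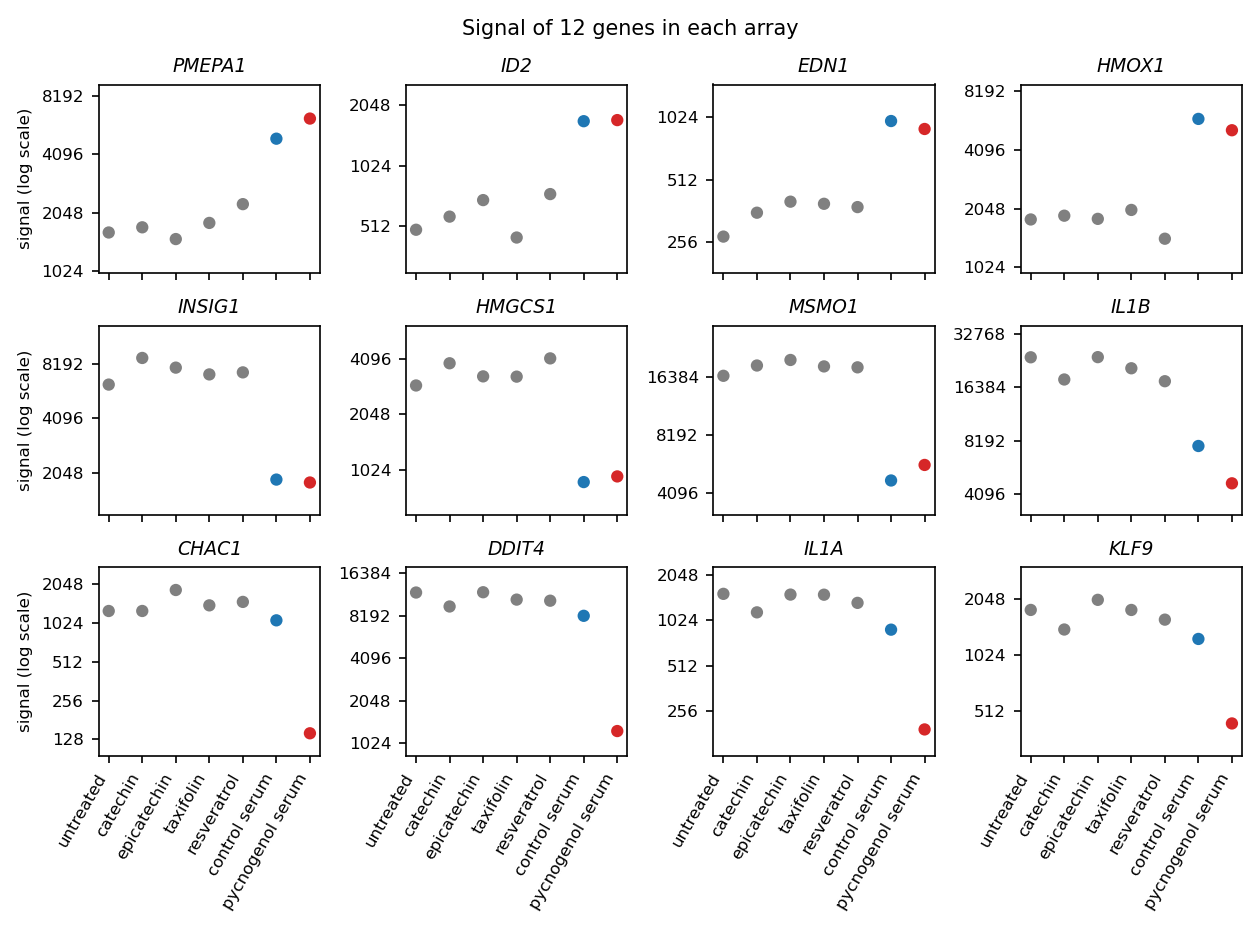
Signal of 12 genes on each of the 7 arrays, with a logarithmic signal axis and 1 point per array. CHAC1 read 1077 with control serum and 143 with pycnogenol serum, and PMEPA1 read 4943 with control serum and 1618 in the untreated culture.

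Each of the 4 compounds gave fewer genes past 2-fold against the untreated culture than control serum did, but without the signal filter resveratrol gave 1982 and control serum 1792. With the mean of the other 3 compound arrays as reference, catechin gave 13 genes, epicatechin 10, taxifolin 14 and resveratrol 25. A mean of arrays holds less noise than 1 array, so these counts are not on the scale of those against the untreated array. Against the other arrays without test serum, the untreated array gave 18 genes and the compounds, in the same order, 10, 7, 10 and 20. With the filter at the 75th percentile against the untreated array the compounds gave 1, 1, 2 and 5. Catechin, a flavan-3-ol, gave 25 higher and 20 lower genes at 2-fold. PPP2R5A, a regulatory subunit of protein phosphatase 2A, was at 1.54 and the histone chaperone DAXX at 1.43, with 0.28 on the second DAXX probe set. MAGEH1 was at 1.196, COA8 at 1.10 with -0.34 on its second probe set, and PARD6B at 1.07. The vitamin K-dependent carboxylase GGCX was at 1.15 with 0.12 on its second probe set, but only 1 of its 4 other probe sets had that direction. Lower genes included SPN, a leukocyte surface sialoprotein read from an _x_at probe set, at -2.54 with a signal of 143, NFIX, a transcription factor, at -1.18 with -0.42 on its second probe set, BRPF1 at -1.07, GFER at -1.06, RAB12 at -1.06 with -0.29 on its second, ADAM15 at -1.02, and ZFX at -1.002 but at 0.26 without _x_at and _s_at probe sets. As groups, 23 of 28 G1/S genes lay above 0 with a median of 0.15, with CCNE2 at 0.52. Of the sterol genes 15 of 18 lay above 0 with a median of 0.18, with NSDHL at 0.61, and all 6 histone genes lay above 0 with a median of 0.31. The ATF4, NF-kB and immediate early lists lay at -0.087, -0.11 and -0.046, outside their ranges, with SESN2, a stress-induced sestrin, at -0.66. Without _x_at and _s_at probe sets the histone median was 0.016 and the ATF4 median -0.019, and the NF-kB and immediate early medians also came inside their ranges, as the sterol median did with the mean of all probe sets.

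Epicatechin gave 16 higher and 15 lower genes, a split of 27 and 10 under quantile normalization. POTEKP, an actin-related pseudogene, was at 1.42, PPP2R5A at 1.33 and the folate receptor FOLR1 at 1.14. GGCX was at 1.08, with -0.099 on its second probe set and 0 of its 4 other probe sets in the called direction. VHL, the substrate receptor of a ubiquitin ligase, was at -1.32, SPN at -1.27, NACA4P at -1.03, and DDX60L at -1.06 but at 0.41 without _x_at and _s_at probe sets. The NF-kB list at -0.12 was alone outside its range, with NFKBIA at -0.65 and RELB at -0.39, and it came inside the range under quantile normalization and both other readings of the probe sets. Taxifolin gave 22 higher and 24 lower genes. PPP2R5A was at 1.25, SNX11, a sorting nexin, at 1.24 with -0.30 on its second probe set, ZDHHC8 at 1.15, and TMEM44 at 1.04 with -0.16 on its second. SPN was at -2.63 with a signal of 135, MNT, a MAX partner that opposes MYC, at -1.41, and SH3PXD2A at -1.35. The kinase MAP3K4 was at -1.34 with -0.49 on its second probe set, TOR2A at -1.12, and NFIX at -1.10 with 0.29 on its second. VANGL1 was at -1.02 with -0.089 on its second, but only 1 of its 3 other probe sets had that direction. Histone genes had a median of 0.28 with H2BC21 at 1.00, G1/S genes 0.11, and AhR and xenobiotic genes 0.20, although GSTM1, a glutathione transferase, was at -1.08. The G1/S median changed sign to -0.0050 with the mean of all probe sets, and without _x_at and _s_at probe sets the histone median was 0.044 and the AhR median came inside its range. IFIT2 was at -1.15, with a signal of 257, but at 0.49 with the mean of its probe sets.

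Resveratrol, a stilbene given at the highest concentration, gave 41 higher and 31 lower genes, a split of 29 and 34 under pairwise loess. DECR2, a peroxisomal enzyme of fatty acid oxidation, was at 2.62 from an untreated signal of 148, DAXX at 1.66 with 0.18 on its second probe set, and PACS2 at 1.38 with 0.030 on its second. PPP2R5A was at 1.09, FOLR1 at 1.04, and TP53BP1 at 1.01 with -0.051 on its second probe set. ADAM15, a membrane metalloprotease, was at -2.33 with a signal of 188, PNRC1 at -1.65, NFIX at -1.52 with -0.54 on its second probe set, CACNG4 at -1.51, RAD54L2 at -1.30, the chromatin remodeller CHD4 at -1.30 with -0.18 on its second, SRRM2 at -1.22 with -0.24 on its second, and MNT at -1.20. THRAP3 lay at -1.21 but at 0.30 without _x_at and _s_at probe sets. Histone genes had a median of 0.36 with H2BC21 at 1.09, G1/S genes 0.19 with 23 of 28 above 0, sterol genes 0.16 and G2/M genes 0.11. The ATF4 list lay at -0.096. The sterol and G2/M medians came inside their ranges with the mean of all probe sets, and the histone and G2/M medians without _x_at and _s_at probe sets. CXCL3, a neutrophil chemokine gene, was at -1.20 and PRKAA2, a catalytic subunit of AMPK, at -1.07.

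In all 4 compounds, 8 genes were higher and FRG1BP was lower by at least 2-fold. They were MAPK11, a p38 kinase, LINC01210, SSH3, ACACB, which makes malonyl-CoA at mitochondria, VPS39, FUOM, PPP2R5A and TVP23C. Of these 9 genes, 7 had an untreated signal under the filter's 269, with MAPK11 at 135 and SSH3 at 122 where the untreated array's median was 128, so the sizes of their differences rest on a reference not shown to be above background. PPP2R5A read 458 in the untreated culture and differed by 1.54, 1.33, 1.25 and 1.09 with catechin, epicatechin, taxifolin and resveratrol, and by 1.17 and 1.04 with control and pycnogenol serum. The compounds shared the untreated array, and simulated unchanged arrays with a shared control gave a mean of 0.36 such genes and a maximum of 3. The simulated noise was normal with 1 SD per expression bin, so these numbers can be too low for noisier probe sets. Correlations across genes between pairs of compounds ran from 0.442 to 0.546, and the simulated value was 0.499, with genes not being independent replicates. Pairs of compounds shared 12 to 20 calls at 2-fold, against 2.66 to 2.88 in the simulation.

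Second probe sets had the called direction for 21 of 42 compound calls, 50% with an interval of 34.2% to 65.8%. These calls pool 4 comparisons with the same untreated array, and genes such as NFIX and SNX11 recur. The interval therefore counts some genes repeatedly and can be too narrow. Unchanged simulated compounds gave 11 to 39 genes at 2-fold, with a mean of 22.8. The 6 pairs of compound arrays, whose spread set that noise, gave 30 to 56. They compare different compounds, so both that spread and those counts can include real differences. The simulation therefore does not settle how many calls noise can give. The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 3.56 with catechin and 4.02 with epicatechin, 3.05 with taxifolin and 2.52 with resveratrol, against 2.40 in the untreated culture, 2.55 with control serum and 2.82 with pycnogenol serum. The GAPDH ratio did not follow it, at 1.05 with catechin and 1.10 with epicatechin, and was highest in the untreated culture at 1.12.

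Catechin and epicatechin are diastereomers, and taxifolin carries a keto group on the central ring that both lack and has the trans configuration of catechin, not the cis configuration of epicatechin. No test or interval was possible for any pair of compounds, and only epicatechin and taxifolin matched in dose, at 6.25 ng/ml. In that pair, 22 genes were higher and 10 lower in epicatechin, with POTEKP at 1.55, MAP3K4 at 1.29, SH3PXD2A at 1.22 and RARS1 at -1.19. Histone genes had a median of -0.30, with 5 of 6 members below 0, G1/S genes -0.082 and immediate early genes 0.075. For catechin at 11.25 ng/ml against epicatechin at 6.25 ng/ml, 12 genes were higher and 18 lower, with the sterol enzyme gene NSDHL at 1.05, POTEKP at -1.81 and PAK1IP1 at -1.10. The sterol and G1/S medians were 0.17 and 0.11, and the immediate early, p53 and TGF-beta medians -0.11, -0.097 and -0.13. Catechin against taxifolin gave 21 higher and 15 lower genes, with MAGEH1 at 1.32 and GFER, a mitochondrial sulfhydryl oxidase, at -1.11. In that pair p53 targets lay at -0.12, hypoxia genes at -0.091, sterol genes at 0.10, immediate early genes at -0.078, ATF4 genes at -0.068 and G1/S genes at 0.067.

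Resveratrol at 2195 ng/ml differed at 2-fold in 51 genes from catechin, 45 from epicatechin and 56 from taxifolin, at doses that were not matched. DECR2 was higher by 1.18 than with epicatechin and by 1.78 than with taxifolin, where its signal was 265. CACNG4, a calcium channel subunit gene, was at -1.50 against catechin, and PNRC1 at -1.55 against epicatechin. Against epicatechin, histone genes had a median of 0.38, sterol genes 0.20, G1/S genes 0.15, immediate early genes -0.13, matrix genes -0.096 and ATF4 genes -0.095. Against taxifolin, G1/S genes lay at 0.12, sterol genes at 0.10, PPAR and lipid genes at -0.16, NF-kB genes at -0.14 and immediate early genes at -0.083. Against catechin, p53 targets at 0.079 were alone outside their range. All 6 pairs together had 26 of 144 list medians outside the range, where 7.2 would be met by chance if all medians were independent. They are not, because the pairs share arrays and the departure of a single array can be counted in several pairs. Genes of a list are not independent replicates either. The value of 7.2 is therefore not the chance level here, and no conclusion was drawn from the excess.

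The comparisons with a control likewise had 26 of 144 list medians outside the range, and 8 of the 26 stayed outside under all 9 alternative settings of processing. Those 8 were heat shock, ATF4, sterol and TGF-beta genes with control serum, ATF4 genes with pycnogenol serum, ATF4 and G1/S genes with resveratrol, and G1/S genes with catechin. The other 18 came to lie inside their range under 1 to 5 of the settings, with the ribosomal protein genes under 5. The 9 settings kept the same reference arrays, and for compounds no list median against a control used another reference. Staying outside therefore cannot tell a compound response from a departure of the shared untreated array. The G1/S median was above 0 in all 6 comparisons, from 0.042 to 0.21. In 12 lists none of the 6 comparisons with a control left the range, and their medians ran from -0.15 to 0.15 as reported. Pycnogenol serum against the untreated array is not one of the 6, and there the angiogenesis median was 0.19 and the clock median 0.16. The 12 lists were the NRF2, p53, apoptosis, matrix, hypoxia, interferon, glucocorticoid, circadian, sirtuin and AMPK, metallothionein, angiogenesis and oxidative phosphorylation lists. Over all 118 medians inside their range, 27 of 1053 values under the alternative settings lay outside with the sign of the reported median, and values outside with the opposite sign were not counted. With control serum the angiogenesis median moved from 0.082 to 0.33 without _x_at and _s_at probe sets, and the sirtuin and AMPK median from -0.050 to -0.23 with the mean of all probe sets. Single members still differed, such as PGF, a placental growth factor gene, at -0.83 with catechin, the clock factor NPAS2 at -0.96 with control serum and BAK1, a mediator of apoptosis, at -0.71 with epicatechin. Of 25 blood cell markers measured, CD79A and HBB lay above the signal filter, at -0.25 and 0.75 with control serum, and at -1.23, with a signal of 198, and 0.87 with resveratrol. The HBB values rest on an untreated signal of 227, and HBB lay at 0.80 with catechin, and at 1.203 with pycnogenol serum against the untreated culture. Of 20 epithelial and endothelial markers, KRT15 and TIE1 lay above it, at -0.89, with a KRT15 signal of 222, and -0.012 with control serum.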

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

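The tests of a shared untreated signal, RNA degradation, blood cell RNA, other splits of the arrays and a departure of the control serum array were chosen only after the results were seen, as was the ratio of 1.2 used for the control probe sets.

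Of 7 quality values read from control probe sets, which no comparison used, 6 cases exceeded 1.2 times the higher of the untreated and control serum arrays. The ratio of 3' to 5' actin signal was 3.56 with catechin and 4.02 with epicatechin, against 2.40 and 2.55 in those controls, and taxifolin at 3.05 lay just under the bound. The GAPDH ratio did not follow, at 1.05 and 1.10 with those compounds and 1.12 in the untreated array, so a difference in RNA integrity was not settled. The signal of the BioB 3' hybridisation control was 1388 with catechin, against 764 and 592, and that of the BioB 5' control was 1320, against 873 and 452. The BioC 3' control read 4195 with catechin and 3237 with taxifolin, against 2452 and 2072. The r2 probe sets of BioB and BioC did not exceed the bound, at 1990 and 4329 with catechin against 1896 and 4852 in the untreated array.

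Control serum differed from the untreated culture in 119 genes at 2-fold. Noise of single probe sets is argued against by second probe sets above the filter, which had the called direction for 86.8% of 38 genes. The rest of the 119 genes had no such probe set and are not covered. For RNA degradation, the control serum actin ratio of 2.55 lay near the untreated 2.40. The sterol median was 0.044 in the epicatechin array, whose actin ratio was highest, but it was made a test only after the results were seen. It covers a single list, noted because it was lower with control serum, so it decides nothing for other genes. For RNA of blood cells carried by the serum, 0 of 25 blood markers rose 2-fold to a signal above the filter. That argues against an amount large enough to lift them there. HBB read 382 against 227, but reached 522 with pycnogenol serum and was also higher, by 0.80 and 0.87 (log2), with catechin and resveratrol. Markers under the filter went both ways, with CD4 at 142 against 13.4, MS4A1 at 120 against 21.4 and LYZ at 6.89 against 77.4. Such signals were not shown to be above background. Both serum arrays against the other 5 gave 66 genes at 2-fold without overlap and the highest of the other splits gave 7, but 1 of 21 is the smallest share these splits allow and the split was tested after the distances had shown it, so it adds little against chance. A response of the cells to the added serum may account for the pattern, but handling of single cultures stays open, because each group was 1 culture.

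For the compounds, 194 calls at 2-fold were made against the untreated array. Noise of single probe sets remains a candidate explanation, since second probe sets had the called direction in 50% of cases. The signal of the shared untreated array likewise remains one, as the mean of the other 3 compounds reached a median share of 0.538 of each called difference, against 0.497 in simulated unchanged arrays, with a range of 0.390 to 0.590. Pairs of compounds shared 12 to 20 calls, against 2.66 to 2.88 simulated, but the simulated noise was normal, so this excess does not decide. Of the 9 genes alike in all 4 compounds, 7 had an untreated signal under the filter, and MAPK11, SSH3 and PPP2R5A were also higher by at least 2-fold in both serum arrays. A response to the compounds was not excluded by these values.

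For pycnogenol serum against control serum, 53 genes differed at 2-fold. Probe set noise cannot be told apart from a real difference over the whole set, since 72.7% of only 11 second probe sets had the called direction, with an interval of 39.0% to 94.0%. A departure of the control serum array alone stays open for part of the genes, because its signal lay farther from the mean of the arrays without test serum for 37.7% of them, 20 of 53. DDIT4 was not among those, at -0.41 with control serum and -3.12 with pycnogenol serum from that mean, and signals of CHAC1 and IL1A with pycnogenol serum, 143 and 193, were too low for a distance. Differences between the sera that are unrelated to pycnogenol were not tested.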

How the results depend on the processing

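The reference arrays used for list medians were chosen only after the data were seen, as were the settings tried on the distances between arrays and on the shared control. No paired analysis was possible because each group was 1 array, and no difference between groups in the report came from a test. The cause of a shift was not tested, except that the filter, the threshold and the choice of probe sets change by construction which genes can be counted. The untreated array as reference also adds the control serum difference to each pycnogenol serum difference by construction. A mean of several arrays as reference holds less noise than 1 array. Quantile normalization, pairwise loess, centring on the median, no floor and a floor at the 40th percentile kept all 12 counts within 1.5 times their value. Of 144 list medians, none moved with centring or the floors, and the 26 outside their range kept their sign under the 3 scalings. Of 4147 values of named genes, 4036 moved less than the spread of genes of like signal, 103 moved more and 8 changed sign. The correlation of compounds that share the untreated array, averaged over pairs of compounds, was 0.491 and ran from 0.465 to 0.510 over the settings. Signal over background limits the counts, since genes under the filter made up most of those counted without it.

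Counts at 2-fold are given in the order catechin, epicatechin, taxifolin, resveratrol, pycnogenol serum and control serum. Without a filter on low signals they were 1664, 1668, 1751, 1982, 1674 and 1792, and with the filter at the 75th percentile 1, 1, 2, 5, 6 and 26. With the mean of all probe sets the first 5 were 98, 85, 84, 123 and 85. Without _x_at and _s_at probe sets they were 119, 100, 113, 162, 120 and 198. The 1.5-fold threshold gave 351, 279, 326, 441, 419 and 774, and the 3-fold threshold 5, 2, 6, 12, 12 and 18. With the other 3 compound arrays as reference the compounds gave 13, 10, 14 and 25. Pycnogenol serum gave 221 with the untreated array as reference, and control serum 64 with the untreated and 4 compound arrays as reference. For the pairs catechin and epicatechin, epicatechin and taxifolin, catechin and taxifolin, then resveratrol with catechin, epicatechin and taxifolin, no filter gave 1537, 1684, 1686, 1849, 1865 and 2031. The filter at the 75th percentile gave 1, 6, 1, 6, 2 and 4, the mean of all probe sets 90, 96, 95, 106, 108 and 113, and leaving out _x_at and _s_at probe sets 115, 123, 126, 120, 132 and 148. The ratio of the median SD of mixed pairs to that of pairs without test serum was 1.37, and it was 1.07 without the filter, 1.52 with the 75th percentile filter, 1.22 with the mean of all probe sets and 1.25 without _x_at and _s_at probe sets.

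With the mean of all probe sets the sign changed for ATF3 (0.15) and MED26 (-0.11) with pycnogenol serum and IFIT2 (0.49) with taxifolin. Without _x_at and _s_at probe sets it changed for DDX60L with epicatechin (0.41), THRAP3 with resveratrol (0.30), ZFX with catechin (0.26), and TRMT10A with control serum (0.16) and pycnogenol serum (-0.14).

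List medians that moved by more than the distance from the centre to the edge of their random range follow, each with its list in parentheses. With the filter at the 75th percentile, the catechin median was -0.30 (NF-kB). For taxifolin under that setting the median was -0.24 (NF-kB). For resveratrol under that setting the medians were -0.49 (NF-kB), -0.015 (apoptosis). For control serum under that setting the medians were -0.32 (NF-kB), -0.76 (sterol), 0.44 (TGF-beta), 0.17 (glucocorticoid). For pycnogenol serum under that setting the median was -0.14 (angiogenesis). Without a filter, the pycnogenol serum median was -0.019 (NF-kB). For control serum under that setting the median was 0.57 (TGF-beta). For resveratrol under that setting the median was 0.14 (angiogenesis). With the untreated array as reference, the pycnogenol serum medians were -0.040 (NF-kB), 0.13 (NRF2), 0.080 (apoptosis), 0.29 (G1/S), 0.36 (heat shock), -0.54 (ATF4), -0.43 (sterol), 0.57 (TGF-beta), 0.16 (clock), -0.34 (PPAR), 0.19 (angiogenesis), 0.31 (histone). Without _x_at and _s_at probe sets, the catechin medians were 0.079 (p53), 0.11 (apoptosis), 0.17 (heat shock), -0.019 (ATF4), 0.016 (histone). For resveratrol under that setting the medians were 0.079 (p53), 0.13 (matrix), 0.22 (heat shock), 0.14 (angiogenesis). For pycnogenol serum under that setting the medians were 0.12 (apoptosis), -0.54 (ATF4), -0.066 (hypoxia), 0.017 (glucocorticoid), 0.17 (metallothionein), 0.044 (ribosomal protein). For control serum under that setting the medians were 0.34 (G1/S), 0.13 (matrix), 0.64 (TGF-beta), 0.16 (glucocorticoid), -0.15 (metallothionein), 0.33 (angiogenesis). For epicatechin under that setting the median was 0.17 (glucocorticoid). For taxifolin under that setting the median was 0.044 (histone). With the mean of all probe sets, the pycnogenol serum medians were 0.11 (p53), 0.060 (apoptosis), -0.11 (angiogenesis). For catechin under that setting the medians were -0.089 (apoptosis), -0.061 (matrix), 0.080 (metallothionein). For epicatechin under that setting the medians were -0.036 (G1/S), -0.050 (heat shock), -0.036 (ATF4), -0.051 (sterol), -0.016 (hypoxia), -0.13 (sirtuin and AMPK), -0.057 (angiogenesis). For taxifolin under that setting the medians were -0.0050 (G1/S), -0.0047 (heat shock), -0.044 (ATF4), 0.0098 (hypoxia), -0.069 (sirtuin and AMPK), -0.093 (angiogenesis). For control serum under that setting the medians were 0.11 (G1/S), 0.53 (TGF-beta), -0.00041 (PPAR), -0.23 (sirtuin and AMPK). With the untreated and 4 compound arrays as reference, the control serum medians were 0.11 (G1/S), 0.61 (TGF-beta). With quantile normalization, the taxifolin medians were 0.017 (hypoxia), -0.0039 (ribosomal protein). For pycnogenol serum under that setting the median was 0.0038 (ribosomal protein). With pairwise loess, the epicatechin medians were -0.027 (ribosomal protein), 0.0074 (oxidative phosphorylation). For taxifolin under that setting the median was -0.018 (ribosomal protein). For pycnogenol serum under that setting the median was 0.030 (ribosomal protein). Among medians that lay outside their random range as reported, the taxifolin G1/S median changed sign with the mean of all probe sets and the pycnogenol serum sterol median with the untreated array as reference. Medians that lay inside their range changed sign as well, such as epicatechin G1/S and heat shock with the mean of all probe sets.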

Other observations

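The comparison of both serum arrays with the other 5 was chosen only after the data were seen, as were its threshold of 1.5-fold and the genes singled out in both accounts that follow.

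Both serum arrays differed from all 5 arrays without test serum by at least 2-fold in the mean, without overlap, in 66 genes, 11 higher and 55 lower. Besides the TGF-beta targets, the higher genes were HMOX1 at 1.63, EDN1 at 1.40, FSTL3, which binds activin and read 249 in the untreated culture, at 1.25, BPGM, which makes a regulator of hemoglobin, at 1.21, the small GTPase gene RHOB at 1.04 and CCL20 at 1.01. Lower genes outside the lists included the matrix protein ECM2 at -1.76 with signals of 206 and 220, the lipoprotein receptor VLDLR at -1.34, CCNG2, a cyclin linked to cell cycle arrest, at -1.22, INHBE, an inhibin beta subunit, at -1.50, and ALDH1L2, a mitochondrial folate enzyme, at -1.09. At 1.5-fold the count was 407 genes, 126 higher and 281 lower. Angiogenesis factors had a median of 0.15 and clock genes one of 0.16, both outside their random ranges, while hypoxia genes at -0.11 and p53 targets at -0.089 lay below theirs.

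Genes of the ATF4 type lay lower against the untreated culture with control serum and lower still with pycnogenol serum. DDIT3, a proapoptotic transcription factor, was at -0.87 and -1.87, TRIB3 at -1.31 and -1.88, SESN2 at -0.86 and -1.58, CTH at -1.06 and -1.60, the cystine transporter SLC7A11 at -0.77 and -1.31, and VEGFA at -0.75 and -1.31. The median of the 30 list members was -0.24 with control serum and -0.54 with pycnogenol serum, with 2 and 10 members lower by at least 2-fold. Over the same arrays TGF-beta targets lay at 0.80 and 0.57, heat shock genes at 0.28 and 0.36, and G1/S genes at 0.21 and 0.29. Set directly against control serum, pycnogenol serum gave medians of 0.018, 0.039 and 0.042 for these lists, all inside their random ranges. The values of 0.80 and 0.57 therefore do not show lower TGF-beta targets with pycnogenol serum than with control serum.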
